A study of Homo sapiens with 4 samples.

How the data were processed

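The series holds 4 arrays of SK-N-AS cells, 2 untreated and 2 treated with BG-P400-TAT at 30 µM for 48 h, which the design text calls biological replicates. How the cultures of one group were separated is not given in the sources used here, so p-values measure the spread between these arrays. Per the labels' protocols, total RNA was extracted with Trizol and labelled with biotin by a whole-transcript sense target protocol. The values deposited by the authors are log2 expression values per probe set, and the submitters' processing notes name RMA and Transcriptome Analysis Console 4.0.1.36. RMA corrects background, quantile-normalizes the arrays and summarizes probes, so a change shared by most genes would be removed by it. The log2 scale was read from the range of the values.

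Of 24351 probe sets, 2903 controls were left out, namely 31 AFFX sets, 2197 positive and 612 negative HTA2 sets and 63 ERCC sets. The other 21448 were tested with no filter on dim signals. In the platform's gene annotation, 17709 probe sets had 1 symbol, 0 had several and 3739 are unnamed here. All 17709 gene identifiers matched the RefSeq gene table of GRCh38.p14, which changed 0 symbols. No genome build is named for the probe sets in the sources used here, and no coordinates are printed. For the 20 symbols with several probe sets, the one with the highest mean was used. A probe set is called above the negative controls where its mean over the 4 arrays exceeds 6.96, the 95th percentile of the negative-control sets, and for single arrays each array's own percentile was used. This background limit was chosen after the data were seen. For a gene below it on all arrays the report gives no fold, and levels in some cases only. Differences of such genes under other settings, printed for ITGB3 and THRB in the closing section, are differences of values below this limit and are not read as changes.

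Treated and untreated arrays were compared on the deposited log2 values with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with group as the only term, two-sided tests and Benjamini-Hochberg adjustment at 0.05. The fit had 2 residual and 4.90 prior degrees of freedom. Confidence intervals are 95% intervals from the same fit. With 2 arrays against 2, an exact permutation test of a single value has 6 arrangements and cannot give a two-sided p below 0.333.

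Gene lists were fixed before the data were examined, 41 lists with 768 genes, of which 682 were measured. Each was tested against all other named genes with camera at a preset correlation of 0.01, with adjustment over the 41 lists. Camera with an estimated correlation and fry were alternatives, and neither called a list. Both draw their p from the 2 residual degrees of freedom, at which hardly any list could pass. The median of each list was also set against 10000 random lists matched on mean expression.

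Genes were named by a rule fixed before the data were examined. It takes the 12 most changed passing genes in each direction whose groups do not overlap, or, where none passes, the 5 with the smallest p, said not to pass. It adds 5 fixed genes and up to 4 genes with the smallest p from each list. The 5 are SLC6A2, ITGAV and ITGB3, which encode the targets named in the series title, and THRA and THRB. Genes named outside the rule are said to be so.

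The fit was tested on simulated data, with variances drawn from the distribution fitted to the real arrays, in 20 simulations of 21448 probe sets with 200 changed by known folds, and 5.34% of the calls were false. Camera was tested in 20 simulations per shift, and called the shifted list in 0 at no shift, 1 at a log2 shift of 0.1, 18 at 0.2 and 20 at 0.3. A list that was not shifted was called 1 time in the 20 simulations at no shift, 0 times at 0.1, 1 time at 0.2 and 0 times at 0.3. The simulated genes varied independently, so these counts do not cover false calls from genes that vary together.

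Alternatives fixed before the data were examined were quantile normalization, median centring, cyclic loess, 2 filters on dim probe sets, a floor, trended and robust variance moderation, the replicate number as a block, each array left out in turn, probe sets with 1 symbol, other thresholds, other set tests and the mean of all probe sets of a gene. Keeping the control sets, keeping only probe sets above the negative controls, and array weights were added after the data were seen.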

Results

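Gene expression was measured in SK-N-AS cells, an established human neuroblastoma line, on Affymetrix whole-transcript arrays. Cells were exposed for 48 h to BG-P400-TAT at 30 µM or to phosphate-buffered saline, called untreated here, with 2 arrays per group. The series title describes the compound as directed at the norepinephrine transporter and at the thyroid hormone-binding integrin αvβ3, and the design text asks which genes respond to it in these cells. The median log2 expression was 6.51 and 6.50 on untreated replicates 1 and 2, and 6.51 and 6.49 on treated replicates 1 and 2. Of the 21448 probe sets tested, 9413 and 8808 lay above the 95th percentile of the negative-control sets on the untreated arrays, and 9657 and 9533 on the treated arrays. Untreated replicate 2 stood apart from the other 3 arrays. Its median absolute log2 difference was 0.244 to untreated replicate 1, 0.237 to treated replicate 1 and 0.242 to treated replicate 2, whereas the pairs without it differed by 0.193, 0.208 and 0.198. The untreated arrays therefore differed from each other more than untreated replicate 1 differed from either treated array. The number of arrays limits the precision of all values.

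The genes of the proteins named in the title were examined first, together with the nuclear thyroid hormone receptor genes THRA and THRB. SLC6A2, which encodes the norepinephrine transporter, had a log2 expression of 9.56 ± 0.36 (SD, n = 2) in untreated and 9.46 ± 0.33 (SD, n = 2) in treated cells. Its log2 fold change was -0.10 with a 95% confidence interval from -0.71 to 0.51, and its sign turned when untreated replicate 2 (0.15) or treated replicate 2 (0.13) was left out. ITGAV, the αv subunit of the integrin, stood at 10.93 ± 0.045 (SD, n = 2) and 10.65 ± 0.035 (SD, n = 2). The log2 fold change of ITGAV was -0.28 (interval -0.71 to 0.15), with a limma adjusted p of 0.949. ITGB3, the β3 subunit, was not above the negative controls on any array, at 5.46 ± 0.30 (SD, n = 2) in untreated and 5.43 ± 0.17 (SD, n = 2) in treated cells. THRA, a nuclear thyroid hormone receptor, stood at 10.88 ± 0.11 and 11.15 ± 0.21 (SD, n = 2 each), a log2 fold change of 0.27 (interval -0.20 to 0.75), which was 0.12 to 0.42 with an array left out. THRB, the other nuclear thyroid hormone receptor, was not above the negative controls on any array, at 5.14 ± 0.29 and 5.15 ± 0.23 (SD, n = 2 each). None of these 5 genes passed the test, and as a list, with 3 of the 5 above the negative controls, they had a camera adjusted p of 0.868.

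**Figure D1:**
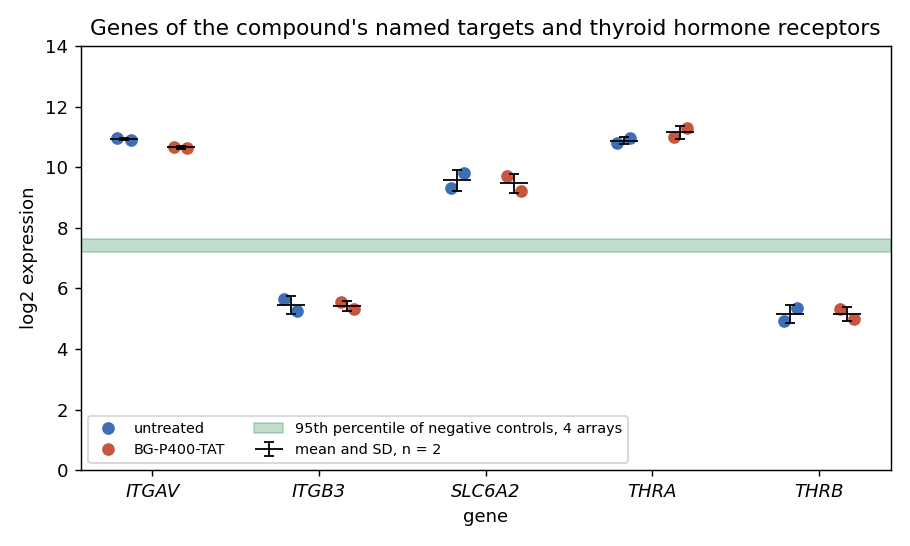
Log2 expression on each array of ITGAV, ITGB3 and SLC6A2, the genes of the compound's named targets, and of THRA and THRB. Group means ± SD (n = 2) are drawn for untreated and treated cells. The green band spans the 95th percentile of the negative-control sets on the 4 arrays. ITGB3 and THRB lie below the band, and no gene passed the test between the groups.

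Across the transcriptome, no probe set differed between treated and untreated cells at a limma adjusted p under 0.05, and the smallest adjusted p was 0.948. At an unadjusted p under 0.05 there were 1089 probe sets, 471 higher and 618 lower in treated cells, where 1072 are expected by chance. This total joins unlike shares: 841 of the 11488 probe sets not above the negative controls (7.32%) and 248 of the 9960 above them (2.49%). MAP1S, which encodes a microtubule-associated protein, was the 1 probe set above the negative controls with a difference of at least 2-fold. Its log2 expression was 8.69 ± 0.12 (SD, n = 2) in untreated and 9.73 ± 0.18 (SD, n = 2) in treated cells, a log2 fold change of 1.04 ± 0.20 (SE) with an interval from 0.57 to 1.51. MAP1S had a limma adjusted p of 0.948 and so did not pass. RNPEPL1, an aminopeptidase-like gene, stood at 6.92 ± 0.20 and 7.85 ± 0.011 (SD, n = 2 each) and was above the negative controls on 2 of the 4 arrays. The other genes with the smallest p among those higher in treated cells were LOC101928198, FER1L6 and FYB2, and all 3 were below the negative controls' 95th percentile on every array. LOC101928198 stood at 2.94 in untreated and 4.11 in treated cells, FER1L6 at 4.17 and 5.10, and FYB2 at 4.03 and 4.96. The 5 genes with the smallest p among those lower in treated cells also lay below that percentile on every array. Their untreated and treated means were 5.50 and 3.87 for CFAP91, 5.42 and 4.17 for PTH2R, 4.42 and 3.17 for HLA-DOB, 4.90 and 3.77 for DSC3, and 4.31 and 2.99 for TSHB. Among the 42 probe sets at least 2-fold apart at any p, 13 were higher and 29 lower in treated cells, and none reached 4-fold.

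**Figure D2:**
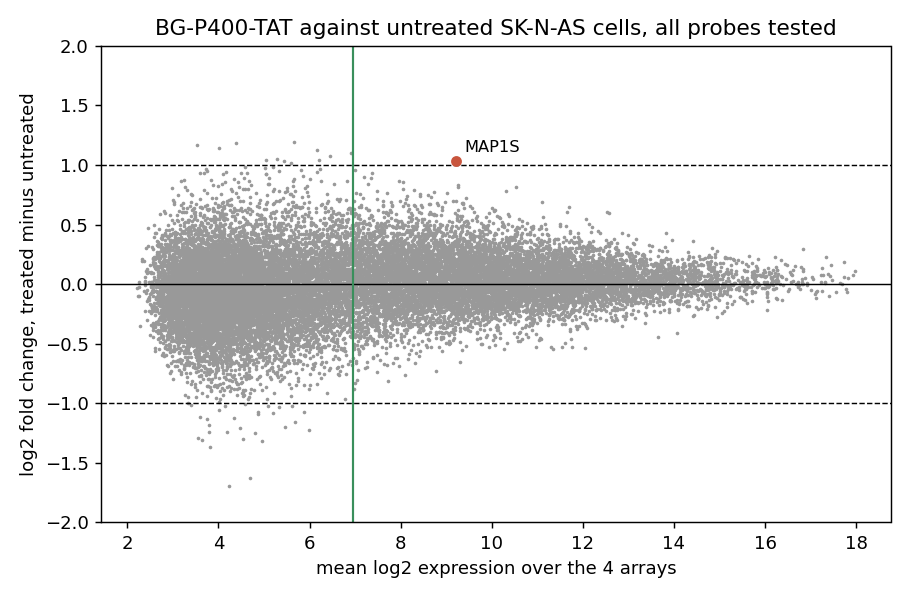
Log2 fold change, treated minus untreated, against mean log2 expression over the 4 arrays for the 21448 probe sets, with dashed lines at a 2-fold difference and a green line at the negative-control cutoff of 6.96. MAP1S is the 1 probe set to the right of the green line and beyond a dashed line.

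Among the 9960 probe sets above the negative controls, 99% had an absolute log2 fold change below 0.62, and 9495 (95.3%) had a confidence interval that lay within 2-fold in both directions. In simulated data of the same size, 200 of 21448 probe sets were changed, 50 each by 1.5-, 2-, 4- and 8-fold. The test called 4.6% of those changed 2-fold, 85.4% of those changed 4-fold and 97.6% of those changed 8-fold. Calls at 4-fold and 8-fold ease the adjusted threshold for the others, so the 4.6% holds for this mix.

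Among 41 gene lists, the hypoxia and glycolysis list was the 1 list that passed limma's camera test (adjusted p = 0.0221). The call was lost in camera with an estimated correlation (adjusted p = 0.81). That setting rests on 2 residual degrees of freedom and could hardly call any list. The correlation estimated for this list was 0.0234, above the preset 0.01, so the degrees of freedom were not the only difference between the settings. Their shares in the loss were not tested apart, and the loss may bear on the list. Of the 26 measured genes of the hypoxia and glycolysis list 24 were higher and 2 lower in treated cells, with a median log2 fold change of 0.16. Most lists leaned the same way: 32 of the 41 medians were positive. Random lists matched to this list on mean expression had a median of 0.032. HK1, which encodes a hexokinase, had a log2 fold change of 0.46 (interval -0.04 to 0.95; 0.27 to 0.65 with an array left out), and EGLN3, an oxygen-sensing prolyl hydroxylase, 0.39 (interval -0.04 to 0.82). P4HA2, a collagen prolyl hydroxylase, had 0.26 (interval -0.17 to 0.69). The mean log2 expression of the list was 11.31 and 11.20 on untreated replicates 1 and 2, and 11.48 and 11.36 on treated replicates 1 and 2. None of the 26 genes passed singly. The call was also lost after quantile normalization (adjusted p = 0.296, median 0.15) or cyclic loess (adjusted p = 0.187, median 0.14). The median stayed at 0.16 and the call was lost with the dimmest probe sets left out (0.0553) or with those below the median left out (0.106). In fry, which tests for movement in one direction, it was lost as well (fry adjusted p = 0.632). Fry also rests on 2 residual degrees of freedom, and its smallest adjusted p over the 41 lists was 0.58. The call was lost too with only the probe sets above the negative controls (camera adjusted p = 0.106, median 0.17). It was lost without untreated replicate 1 (0.056, median 0.21), untreated replicate 2 (0.335, median 0.13) or treated replicate 1 (0.285, median 0.12). VEGFA, an angiogenic growth factor on this list, had a log2 fold change of -0.05 (interval -0.52 to 0.42), and HIF1A, a subunit of the hypoxia-inducible factor, 0.024 (interval -0.54 to 0.59). VEGFA, HIF1A, MKI67, TOP2A and BIRC5 were chosen for mention after their values were seen. The sign of VEGFA turned without treated replicate 2 (0.098), and that of HIF1A without untreated replicate 2 (-0.26), without treated replicate 2 (-0.0016) and after cyclic loess (-0.00074).

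The other metabolic lists did not pass. In fatty acid synthesis 8 of 10 genes were positive, with a median of 0.20 (camera adjusted p = 0.187), and FASN, the fatty acid synthase, had a log2 fold change of 0.36 (interval -0.08 to 0.79). ACACA, an acetyl-CoA carboxylase, had 0.42 (interval -0.16 to 1.00). In cholesterol synthesis and uptake 13 of 19 genes were positive (median 0.030, camera adjusted p = 0.711), with PMVK, phosphomevalonate kinase, at 0.49 and STARD4 at -0.32. In oxidative phosphorylation 19 of 21 were positive (median 0.064, camera adjusted p = 0.231), with ATP5F1C, an ATP synthase subunit, at 0.24. In lysosome and autophagy 17 of 23 were positive (median 0.063, camera adjusted p = 0.299), with the autophagy kinase gene ULK1 at 0.49 and the lysosomal protease gene CTSD at 0.33. The cholesterol median turned negative after quantile normalization, after cyclic loess and without untreated replicate 1 (-0.010), and the lysosome median without untreated replicate 2 (-0.0038). Leaving out an array gave medians of 0.13 to 0.27 for fatty acid synthesis and 0.042 to 0.13 for oxidative phosphorylation, and fold changes on the log2 scale of 0.13 to 0.71 for ACACA, 0.26 to 0.73 for PMVK and 0.30 to 0.68 for ULK1.

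Proliferation and cell death genes likewise gave no call. In the mitosis list 17 of 29 genes were positive (median 0.015, camera adjusted p = 0.594), with the kinetochore genes CENPE at -0.53 (interval -1.13 to 0.07) and CENPA at 0.32. MKI67, a proliferation marker, had a log2 fold change of -0.09 (interval -0.54 to 0.36) and TOP2A, a DNA topoisomerase, 0.015 (interval -0.43 to 0.46). The sign of MKI67 turned without treated replicate 2 (0.0059), and that of TOP2A after quantile normalization, after cyclic loess, without untreated replicate 1 and without treated replicate 1. BIRC5, which encodes survivin, had 0.15 (interval -0.30 to 0.59). In DNA replication and G1/S 22 of 28 were positive (median 0.10, camera adjusted p = 0.114), with the replicative helicase gene MCM6 at 0.36. In replication-dependent histones 15 of 19 were positive (median 0.017, camera adjusted p = 0.523), with H2AC6 at 0.35 and H1-5 at 0.23. In homologous recombination and DNA repair 9 of 15 were positive (median 0.019, mean -9.23e-05, camera adjusted p = 0.971, direction down), so the median differed in sign from the mean and the test. CHEK1, a checkpoint kinase of that list, had -0.41 (interval -0.84 to 0.03). BARD1 of the same list had -0.45 (interval -0.90 to -0.0029) and RAD54L 0.45 (interval -0.09 to 0.99). In p53 targets 11 of 19 were positive (median 0.031, camera adjusted p = 0.715), with the death receptor gene TNFRSF10B at 0.34 (interval -0.10 to 0.77). In death-promoting apoptosis genes 16 of 22 were positive (median 0.11, camera adjusted p = 0.247). In survival-promoting genes 6 of 12 were positive (median 0.060, camera adjusted p = 0.711), with AKT1 at 0.47 and BCL2L2 at -0.34. In MYC targets and ribosome biogenesis 11 of 18 were positive (median 0.060, camera adjusted p = 0.402), with SRM, spermidine synthase, at 0.45. Several of these medians turned negative when an array was left out: mitosis without untreated replicate 2 (-0.022), histones without treated replicate 2 (-0.082), p53 targets without untreated replicate 2 (-0.080), DNA repair without untreated replicate 2 (-0.016) or treated replicate 1 (-0.031), and survival genes without untreated replicate 1 (-0.0038) or treated replicate 1 (-0.024). Quantile normalization and cyclic loess turned those of mitosis, histones and DNA repair, cyclic loess that of p53 targets, and the filters at the median and at the negative controls that of survival genes. With an array left out, the medians were 0.064 to 0.15 for DNA replication, 0.057 to 0.19 for death-promoting genes and 0.063 to 0.091 for MYC targets. The log2 fold changes were then -0.86 to -0.20 for CENPE, 0.21 to 0.42 for CENPA, 0.062 to 0.24 for BIRC5, 0.16 to 0.53 for H2AC6, 0.090 to 0.37 for H1-5, 0.22 to 0.73 for AKT1 and -0.60 to -0.077 for BCL2L2.

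Neuroblastoma identity and catecholamine genes also stayed below the threshold. In the adrenergic identity list 8 of 14 genes were positive (median 0.10, camera adjusted p = 0.537). PHOX2A, a transcription factor of sympathetic neurons, had a log2 fold change of 0.58 (interval 0.11 to 1.05) and GATA2 had 0.42. MYCN was not above the negative controls on any array. In the mesenchymal identity list 14 of 21 were positive (median 0.11, camera adjusted p = 0.231), with the transcriptional co-activator gene YAP1 at 0.42 and TWIST1 at 0.40. In catecholamine synthesis, storage and uptake 8 of 15 were positive (median 0.040, camera adjusted p = 0.627), with CYB561, a cytochrome of secretory granules, at 0.61 (interval 0.16 to 1.06). PNMT, the epinephrine-forming enzyme, was not above the negative controls on any array, at 5.70 and 5.08. In neuronal structure and differentiation 9 of 22 were positive (median -0.056, camera adjusted p = 0.627), with the neurofilament gene NEFL at 0.29. In thyroid hormone response 4 of 14 were positive (median -0.22, camera adjusted p = 0.248), and 3 of the 14 were above the negative controls. KLF9, a thyroid hormone-induced transcription factor, was not among them, at 6.41 and 6.99. The catecholamine median was -0.072 without untreated replicate 2, and the neuronal median 0.015 without untreated replicate 1. Single arrays also moved the medians, to 0.028 to 0.11 for adrenergic identity, 0.011 to 0.18 for mesenchymal identity and -0.21 to -0.14 for thyroid hormone response, and the log2 fold changes, to 0.22 to 0.62 for GATA2, 0.24 to 0.55 for TWIST1 and 0.17 to 0.42 for NEFL.

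Adhesion, matrix and signalling lists gave the following values. In integrin subunits 6 of 17 were positive (median -0.09, camera adjusted p = 0.782), with ITGA11, a collagen-binding subunit, at 0.78 (interval 0.29 to 1.27) and ITGA5, a fibronectin-binding subunit, at 0.31. In angiogenesis 13 of 24 were positive (median 0.021, camera adjusted p = 0.782), with PGF, placental growth factor, at -0.41 and VEGFB at 0.31 (interval -0.18 to 0.79). In collagens and extracellular matrix 16 of 24 were positive (median 0.081, camera adjusted p = 0.688), with FN1, fibronectin, at 0.38. In TGF-beta targets 12 of 16 were positive (median 0.15, camera adjusted p = 0.106), with the inhibitory gene SMAD6 at 0.55 (interval 0.08 to 1.01) and ID3 at 0.49. In YAP and TEAD targets 10 of 19 were positive (median 0.093, camera adjusted p = 0.231), and ANKRD1 was not above the negative controls on any array. In immediate early genes and ERK feedback 16 of 22 were positive (median 0.12, camera adjusted p = 0.248), with FOSL1, an AP-1 subunit, at 0.45. In Wnt and beta-catenin targets 9 of 14 were positive (median 0.095, camera adjusted p = 0.523), with CTNNB1, β-catenin, at 0.36. Genes above the negative controls numbered 10 in the angiogenesis list, 9 in YAP and TEAD targets and 6 in Wnt targets. The YAP and TEAD median was -0.11 without treated replicate 1 and turned negative under all 3 filters on dim probe sets. The angiogenesis median was -0.023 without untreated replicate 2 and -0.083 without treated replicate 1, and the integrin median was 0.071 among genes above the negative controls or above the median of all probe sets. Medians with an array left out were -0.19 to -0.050 for integrins, 0.0014 to 0.14 for collagens and matrix, 0.10 to 0.19 for TGF-beta targets and 0.051 to 0.15 for immediate early genes. Single log2 fold changes were then -0.67 to -0.15 for PGF, 0.011 to 0.75 for FN1, 0.18 to 0.80 for ID3, 0.15 to 0.74 for FOSL1 and 0.11 to 0.62 for CTNNB1.

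Stress and inflammatory lists did not pass either. In the NRF2 oxidative stress response 14 of 18 genes were positive (median 0.15, camera adjusted p = 0.106), with AKR1C1 at 0.36 and TKT, transketolase, at 0.32. In endoplasmic reticulum chaperones and the XBP1 response 12 of 19 were positive (median 0.13, camera adjusted p = 0.231), with PDIA4, a disulfide isomerase, at 0.31. In the ATF4 and amino acid stress response 13 of 24 were positive (median 0.017, camera adjusted p = 0.813). CHAC1 and DDIT3 of that list were not above the negative controls on any array. In the heat shock response 11 of 16 were positive (median 0.086, camera adjusted p = 0.402), with HSPA1A at 0.28. In metallothioneins and zinc export 6 of 9 were positive (median 0.062, camera adjusted p = 0.874), with MT1M at -0.46 and the zinc exporter gene SLC30A1 at 0.39, which was -0.059 without untreated replicate 2. In the type I interferon response 13 of 25 were positive (median 0.016, mean -0.024, camera adjusted p = 0.847, direction down), so the median differed in sign from the mean and the test. In NF-kB and inflammatory cytokines 10 of 19 were positive (median 0.0069, camera adjusted p = 0.688), with the chemokine gene CCL2 at 0.33. In the proteasome 17 of 22 were positive (median 0.078, camera adjusted p = 0.247), with PSMB5 at 0.31. In cytosolic ribosomal proteins 8 of 12 were positive (median 0.051, camera adjusted p = 0.711), with RPS6 at 0.11, which was -0.046 without untreated replicate 2. Genes above the negative controls numbered 12 in the ATF4 list, 9 in the interferon list and 7 in the NF-kB list. The ATF4 median turned negative after cyclic loess and without untreated replicate 2 (-0.0069) or treated replicate 1 (-0.031), the NF-kB median without untreated replicate 1 (-0.059), the metallothionein median without untreated replicate 2 (-0.031) or treated replicate 2 (-0.075) and the ribosomal median without treated replicate 2 (-0.015). The interferon median turned negative under the filters at the median and at the negative controls, and without untreated replicate 2 (-0.035), treated replicate 1 (-0.0095) or treated replicate 2 (-0.054). With an array left out, medians ran from 0.079 to 0.13 for endoplasmic reticulum chaperones, 0.010 to 0.12 for heat shock and 0.032 to 0.16 for the proteasome, and log2 fold changes from 0.20 to 0.44 for TKT, 0.20 to 0.41 for PDIA4, 0.16 to 0.40 for HSPA1A, -0.70 to -0.22 for MT1M and 0.16 to 0.50 for CCL2. No gene of the 41 lists passed over all probe sets tested, and 0 passed when adjusted over the list alone.

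**Figure D3:**
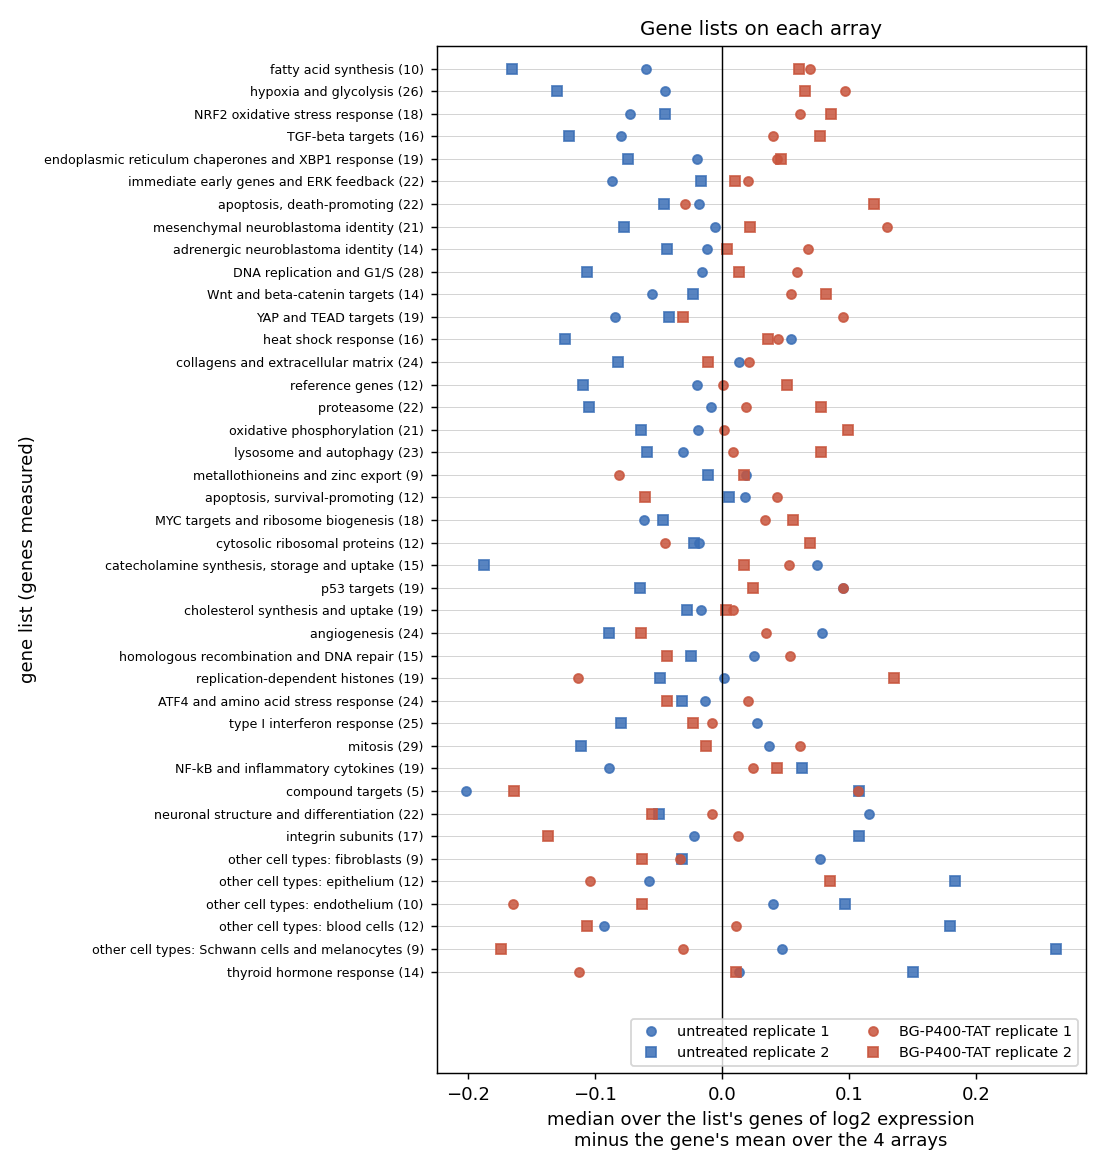
Median over each list's measured genes (number in parentheses) of log2 expression minus the gene's mean over the 4 arrays, for each array; circles are replicate 1, squares replicate 2, blue untreated and red treated. In the hypoxia and glycolysis list both treated arrays lie to the right of both untreated arrays, and untreated replicate 2 lies farthest to the left.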

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

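The filter at the negative controls, the control sets kept and the array weights were chosen after the data were seen. The count of probe sets changed, higher, lower or changed at least 2-fold at a limma adjusted p under 0.05 was 0 under each of these and under each other setting for that threshold, including without each array in turn. Under an unadjusted p under 0.05 with a 2-fold difference, 39 probe sets passed, 11 higher and 28 lower, and 1 of these was above the negative controls. The same rule gave 28 and 40 probe sets in the other splits of the 4 arrays into pairs. The number at an unadjusted p under 0.05 was 1089 and ranged from 690 to 2444 when an array was left out, with 2444 without untreated replicate 1, 741 without treated replicate 1 and 690 without treated replicate 2. A lone array is then assumed to vary like the other group.

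The list count of 1 became 0 with quantile normalization, cyclic loess, either filter on dim probe sets, the filter at the negative controls, an estimated correlation and fry. It became 6 with a floor at the 25th percentile, and ranged from 0 to 1 when an array was left out. The floor raised all values under 4.30 to that level. The prior degrees of freedom of the probe-set fit were then 0.438, against 4.90 on the deposited values, so its variance estimates are not like those of the main fit. The cause of these counts was not tested. The adjusted p of the hypoxia and glycolysis list ranged from 0.000555 with the floor to 0.81 with an estimated correlation, and its median from 0.12 to 0.21. With the replicate number as a replicate block, 0 probe sets passed, 1079 had an unadjusted p under 0.05, and 1 list passed (adjusted p = 0.0264). Deviations of arrays with the same number had a correlation of -0.000849 across probe sets, so the numbers were not taken to pair the arrays. Array weights came out equal within a group and could not lower the weight of a single array.

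Of 107 genes followed, 3 turned sign under a setting other than leaving out an array, and 9 when an array was left out. TOP2A was -0.019 after quantile normalization and -0.014 after cyclic loess, and HIF1A -0.00074 after cyclic loess; the cause was not tested. The third was ITGB3, which like THRB lay below the negative controls on all arrays, so that the sign of its difference between groups carries no meaning. The log2 difference of ITGB3 was 0.031 and 0.014 under these normalizations, and leaving out an array gave -0.24 to 0.18 for ITGB3 and -0.21 to 0.21 for THRB. Leaving out an array gave ranges of -0.35 to 0.15 for SLC6A2, -0.059 to 0.84 for SLC30A1, -0.046 to 0.26 for RPS6, -0.077 to 0.11 for TOP2A, -0.26 to 0.31 for HIF1A, -0.20 to 0.098 for VEGFA and -0.18 to 0.0059 for MKI67. Leaving out an array moved 58 of the 107 genes and 38 of the 41 list medians by over 1.5 times or turned them. Of the 41 list medians, 11 changed sign under such a setting and 20 without an array. Genes removed by a filter have no value under it. Probe sets near the negative controls limit what can be read, since 11488 of 21448 lie at or below that level.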

Other observations

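All tests of explanations below were chosen after the result was seen, except the test of pair differences after cyclic loess. Markers of other cell types were used as checks of the cultures. In the blood cell list 3 of 12 genes were positive (median -0.13, camera adjusted p = 0.435), in endothelium 2 of 10 (median -0.11, camera adjusted p = 0.247) and in Schwann cells and melanocytes 1 of 9 (median -0.13, camera adjusted p = 0.106). Above the negative controls were 3 of the 12 blood, 1 of the 10 endothelium, 4 of the 12 epithelium and 0 of the 9 Schwann cell and melanocyte genes. These signs therefore rest mostly on values below the background limit. In epithelium 4 of 12 were positive (median -0.11, camera adjusted p = 0.711), with the keratin gene KRT18 at a log2 fold change of 0.66 (interval 0.06 to 1.27). In fibroblasts 4 of 9 were positive (median -0.10, camera adjusted p = 0.874), with the surface glycoprotein gene THY1 at 0.65 (interval 0.17 to 1.13) and COL1A1 at -0.28. Unlike in the other cell type lists, 8 of the 9 fibroblast genes were above the negative controls, with a list mean log2 expression of 10.2. Genes of the fibroblast list were thus expressed in these cultures, treated or not. Among reference genes 10 of 12 were positive (median 0.080, camera adjusted p = 0.450), with HPRT1 at 0.22. The blood median was 0.028 without untreated replicate 2, the epithelium median 0.081 without untreated replicate 2 and 0.029 without treated replicate 1, and the fibroblast median 0.0045 without untreated replicate 1 and 0.013 without untreated replicate 2. With an array left out, medians were -0.21 to -0.017 for endothelium, -0.37 to -0.079 for Schwann cells and melanocytes and 0.012 to 0.15 for reference genes, and KRT18 was 0.33 to 0.99. No gene of these lists passed.

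Untreated replicate 2 differed from the other 3 arrays more than those differed from each other. A compressed signal range on that array is a candidate explanation: across probe sets its deviation from the other arrays fell with brightness (Spearman -0.278), and the gap between positive and negative controls was 8.86 against 9.04, 9.04 and 9.17. As the whole cause this is argued against by cyclic loess, after which its smallest median absolute difference was 0.226 and the highest among the other pairs 0.208. No biological explanation was tested for a single array.

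The hypoxia and glycolysis list lay higher on both treated arrays, with list means of 11.48 and 11.36 against 11.31 and 11.20. Random lists matched on brightness had a median of 0.032, and the median of this list lay at percentile 99.99 among them. After cyclic loess its median was 0.14, though the camera call was lost. A brightness trend as the whole of the shift is argued against by these medians. The percentile is no test of the list, which was picked as the 1 passing of 41. The random genes were drawn singly, without shared variation. Lists that did not pass also lay far out, fatty acid synthesis at 99.89 and thyroid hormone response at 1.31. Without untreated replicate 2 the median of the list was 0.131, against 0.164 with all arrays. Whether that array alone gave rise to the call cannot be told. Untreated replicate 1 is then the only untreated array, at 11.31, so the spread of its group is unknown. The treated arrays, at 11.48 and 11.36, also differ from each other. Whether the treatment shifted the list stays open, because the exact permutation p of 0.333 is the smallest that 2 arrays against 2 allow.

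No probe set passed the test between treated and untreated cells. A change in many bright probe sets, diluted by dim ones, is argued against. Of the 9960 above the negative controls, 5.11% had an unadjusted p under 0.05 in a fit of their own. The share was 2.49% in the fit of all probe sets, whose shared variance is set partly by dim ones. A change in few bright probe sets would hardly move these shares, so they cannot exclude it. Whether a treated and an untreated array were exchanged cannot be told: the smallest adjusted p of the other splits was 0.945, but in the simulation the test called 4.6% of 2-fold changes. The real split gave 1089 probe sets at an unadjusted p under 0.05 and the highest other split 1034, as 1 of 3 splits, which are too few for a share under 0.05. A response smaller than the test could call may remain, given that 5.11% and the detection limits of 2 arrays per group.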
